A study of Mus musculus with 12 samples.

How the data were processed

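RNA sequencing of mouse bone marrow-derived mesenchymal stem cells was analysed in 12 libraries, 3 in each of 4 groups: untreated cells (Ctrl), cells treated with CK666, cells treated with cytochalasin D (CytoD), and cells treated with both. Per the labels, cells were cultured in medium with 10% serum, plated at 10000 cells per square centimetre, kept for 1 day and then treated for 24 h. Concentrations of the compounds are not given in the sources used here, and the labels do not say whether replicates are separate animals, isolations or cultures.

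The count values were analysed as deposited: the authors' table gives the number of reads assigned to each gene, per the file headers, and their processing notes name CASAVA 1.9, TopHat, HTSeq and the human build hg19. The RPKM values in the same table were made by the authors from those counts, per kilobase of the length column and per a total for each library that exceeded the sum of gene counts by a factor of 1.122 to 1.162. The RPKM values were used only to derive that total, from which the share of reads not counted in gene rows was taken. Where those reads lie in the genome was not seen. The named build is human, while symbols are those of mouse genes and coordinates match the mouse build GRCm38: of 20970 rows matched by name to GENCODE M21, 99.4% overlapped the gene of that name and 83.2% ended within 1000 bases of it. Every count in the table was even, which would follow if both reads of a fragment were counted. Counting error would then be larger than the counts imply, and halved counts were tried as an alternative. The table has 23358 rows with 23315 distinct symbols, and 69 rows whose symbol occurs more than once were kept as separate rows. No gene encoded by mitochondrial DNA was found under the symbols searched, so that list was left out. The ribosomal RNA gene Rn45s took 1.856% to 4.521% of the counts per library. Some rows overlap others, and reads of near-identical genes cannot be assigned with certainty.

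The sum of gene counts per library was between 48930210 and 69269716. A count of 0 allows up to 3 counts, or 0.0613 CPM (counts scaled to a common library total) in the shallowest library, a limit that covers counting error only. If both reads of a fragment were counted, this limit is higher. Genes were kept with edgeR's filterByExpr (minimum count 10), which left 13534. Libraries were scaled by TMM, and a quasi-likelihood model with a mean for each of the 4 groups was fitted in edgeR 4.0.16 under R 4.3.3. The common biological coefficient of variation was 0.115 and the median prior degrees of freedom 4.79. The tests were 2-sided, p values were adjusted by Benjamini and Hochberg within each comparison, and genes with an adjusted p under 0.05 were called. The SE of a log2 fold change is its size over the square root of the F statistic. Levels are TMM-scaled CPM without a pseudocount, with the SD over 3 libraries, while log2 CPM for the principal components and camera used a prior count of 2.

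The comparisons were CytoD against Ctrl, CK666 against Ctrl, both against each compound alone, both against Ctrl, and the interaction, which is the change with CytoD in the presence of CK666 minus that in its absence. These, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. A comparison of CK666 with CytoD, the halved counts, the removal of Rn45s and a correction for gene length were added afterwards. With 7 comparisons in all, no adjustment was made across comparisons.

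The 28 gene lists held 471 entries, of which 456 were found, 10 of them under an older symbol, and 27 lists were tested: osteoblast, adipocyte, chondrocyte, smooth muscle contractile, SRF and MRTF targets, YAP and TAZ targets, Arp2/3 complex and activators, actin turnover and nuclear transport, focal adhesion and integrins, fibrillar matrix, matrix proteases and inhibitors, mitosis, DNA replication, p53 targets, interferon response, inflammatory cytokines and NF-kB targets, cholesterol synthesis, glycolysis and hypoxia, unfolded protein and integrated stress response, Wnt targets, BMP targets, nuclear lamina and LINC complex, tubulins, and markers of marrow stromal, macrophage, endothelial, and erythroid and lymphoid cells. Each was tested with camera in limma 3.58.1 at the preset correlation of 0.01 and with an estimated correlation, and with fry. The rule for named genes took, in the first 3 comparisons, the 6 most raised and the 6 most lowered called genes whose groups did not overlap, called members of the lists with the largest changes, and a set fixed in advance: Sp7, Runx2, Alpl, Bglap, Ibsp, Spp1, Pparg, Cebpa, Fabp4, Adipoq, Plin1, Lpl, Acta2, Tagln, Ctgf, Cyr61, Actb, Actr2, Actr3 and Srf. The other comparisons took fewer genes by the same rule. The genes printed are part of those the rule names, picked after their values were seen, and some genes that the rule names are not reported here.

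The alternatives were RLE size factors in edgeR, the Wald test of DESeq2 1.42.0, no filter and a stricter filter on low counts, the replicate number as a block, a fit of the compared groups alone, each library left out in turn, halved counts, removal of Rn45s and a correction for gene length in each library. The pipeline was tested on simulated counts for 12 libraries in 4 groups. These were made from the mean levels, spread and totals of all 12 libraries, and changes at known folds were planted in CytoD alone.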

Results

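RNA was sequenced from mouse bone marrow-derived mesenchymal stem cells, adherent stromal cells of the marrow that can give rise to bone, fat and cartilage cells. The cells were left untreated (Ctrl), or were treated for 24 h with cytochalasin D (CytoD), a fungal compound that caps the growing ends of actin filaments, with CK666, an inhibitor of the Arp2/3 complex that starts branches on actin filaments, or with both compounds. Each of the 4 groups had 3 libraries, and 12 libraries were analysed. The sum of gene counts per library lay between 48930210 in CytoD replicate 1 and 69269716 in replicate 2 of the combination. A count of 0 allows a level of up to 0.0613 CPM (counts scaled to a common library total) in the shallowest library, a floor of 3 counts that covers counting error only. Every count was even, and the floor is higher if both reads of a fragment were counted. Levels below are TMM-normalized CPM with the SD over n = 3 libraries, log2 fold changes carry their standard error (SE), and adjusted p values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13534 genes. Coordinates are those of the deposited table. What the labels call replicates is not described further, so p values measure the spread between these libraries, which may be technical.

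The libraries separated by treatment. On the first principal component, with 55.6% of the variance, Ctrl libraries lay lowest, CytoD libraries next and the CK666 and combination libraries highest, and the second component, with 25.1%, set the CytoD libraries apart. CK666 replicate 3 stood apart from the other CK666 libraries, with a median absolute log2 difference of 0.259 and 0.254 from replicates 1 and 2, against 0.098 between those. Its difference from them went with gene length (Pearson r = -0.659 across genes, which are not independent replicates). No pair of replicates differed by so little as to be one library deposited more than once, since the chi-square per degree of freedom was at least 5.9.

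**Figure D1:**
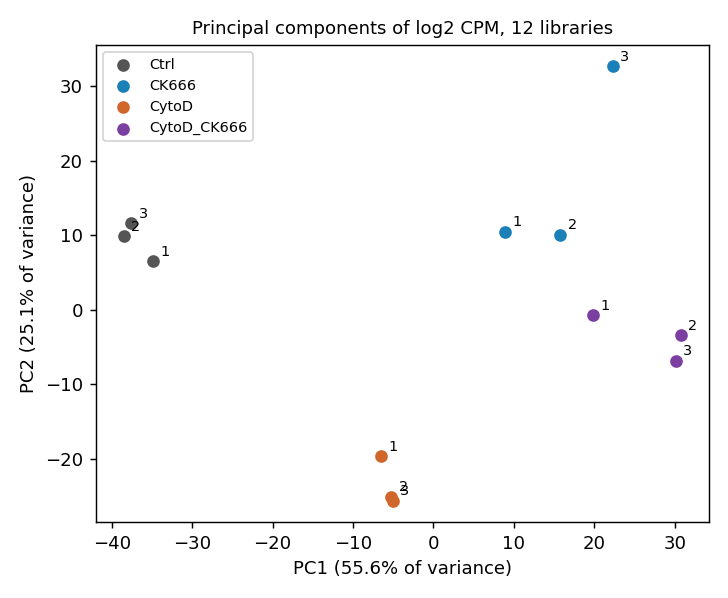
Principal components of log2 CPM over 10193 genes in the 12 libraries, with one point per library, coloured by group and numbered by replicate (axes are component scores, with percent of variance). CK666 replicate 3 lies at 32.7 on the second component, while the other CK666 libraries lie at 10.48 and 10.11.

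The first comparison asked which differentiation genes changed when actin filaments were disrupted with CytoD. Genes of fat cells rose, those of contractile and dividing cells fell, and genes of bone-forming cells moved both ways. Of 25 adipocyte genes tested, 20 rose and 1 fell (21 and 1 adjusted over the list alone). Plin1, a coat protein of lipid droplets (chromosome 7, 79721164 to 79732776), rose from 6.97 ± 0.791 CPM to 141 ± 2.71 CPM (log2 4.34, SE 0.21). Adipoq, which encodes the hormone adiponectin (chromosome 16, 23146536 to 23157968), was 9.41-fold higher, and Cd36, a fatty acid transporter, 17.0-fold higher from a level of 0.492 ± 0.0704 CPM. The transcription factors Pparg and Cebpa, which drive adipocyte formation, rose 1.51-fold and 1.78-fold. Lpl, lipoprotein lipase, rose 2.4-fold. Fabp4, a fatty acid carrier, was 1.53-fold higher (adjusted p = 0.0168), a call that was lost without Ctrl replicate 1 (adjusted p = 0.0537), Ctrl replicate 2 (adjusted p = 0.0655) or CytoD replicate 3 (adjusted p = 0.0532).

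Of 19 osteoblast genes, 9 rose and 5 fell after CytoD (10 and 5 adjusted over the list alone). Runx2, the transcription factor required for bone formation (chromosome 17, 44604001 to 44814797), rose from 65.7 ± 1.66 to 90.9 ± 3.0 CPM, and part of its span overlaps Supt3h. Alpl, the alkaline phosphatase of mineralizing cells, rose 4.82-fold from 3.86 ± 1.1 CPM, and Pth1r, the parathyroid hormone receptor, 5.05-fold from 0.369 ± 0.136 CPM. Sp7, a transcription factor downstream of Runx2, was measured at 0.614 ± 0.523 CPM in Ctrl and 2.21 ± 1.09 CPM in CytoD (adjusted p = 0.0294), and the call was lost when any of Ctrl replicates 1 and 2 or CytoD replicates 2 and 3 was left out (adjusted p = 0.0676, 0.0766, 0.114 and 0.0866) or with DESeq2 (adjusted p = 0.0501). The bone matrix genes Bglap and Ibsp stayed near the floor, at 0.0266 ± 0.0232 and 0.0277 ± 0.024 CPM in Ctrl and 0.156 ± 0.068 and 0.154 ± 0.106 CPM in CytoD. The call of Bglap (adjusted p = 0.0313) was lost in 5 of 6 fits without 1 library (adjusted p = 0.0553 to 0.106), while Ibsp (adjusted p = 0.0521) was called with DESeq2 (adjusted p = 0.0424), with the length correction (adjusted p = 0.0406) or without CytoD replicate 1 (adjusted p = 0.0254). Spp1, osteopontin, was measured at 10170 ± 189 CPM in Ctrl and 8998 ± 695 CPM in CytoD (adjusted p = 0.466, and 0.0187 when the fit held these 2 groups alone). Of 11 BMP target genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone), among them Id4, 5.49-fold higher, and Atoh8, 1.96-fold higher.

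Of 13 contractile smooth muscle genes, 10 fell and 1 rose after CytoD (10 and 1 adjusted over the list alone). Acta2, smooth muscle actin (chromosome 19, 34241091 to 34255336), fell from 3042 ± 69.2 to 498 ± 20.2 CPM, 6.11-fold lower, and Tagln, transgelin, whose span touches that of Pcsk7, was 4.4-fold lower. Actg2 was 4.68-fold lower, although reads of near-identical actin genes could have been split between Acta2, Actg2 and Actb. Of 15 targets of the actin-regulated factors SRF and MRTF, 14 fell and 0 rose (14 and 0 adjusted over the list alone), including Fhl1, 5.25-fold lower, and Vcl, which encodes vinculin, 2.13-fold lower. Of 22 targets of YAP and TAZ, 8 fell and 2 rose (8 and 2 adjusted over the list alone), with Ctgf, a secreted matrix-cell protein (chromosome 10, 24595442 to 24598682), 8.49-fold lower and Cyr61 2.24-fold lower. Among focal adhesion genes and integrins 16 of 22 fell and 2 rose (16 and 2 adjusted over the list alone). Itga5 was 2.51-fold lower and Itga1 5.11-fold higher, although the span of Itga1 holds Pelo. Actr3, a subunit of the Arp2/3 complex, fell from 605 ± 23.1 to 394 ± 11.6 CPM, while Actr2 was measured at 317 ± 11.9 and 297 ± 11.7 CPM (adjusted p = 0.399).

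Genes of cell division and of sterol synthesis fell after CytoD. All 20 mitosis genes and all 21 DNA replication genes tested fell (20 and 21 adjusted over the list alone), among them Aurka, a mitotic kinase, 2.78-fold lower, and Mcm5, a subunit of the replicative helicase, 3.41-fold lower. Ccna2, cyclin A2, was 2.69-fold lower and shares part of its span with Exosc9. Of 20 genes of cholesterol synthesis 19 fell and 0 rose (19 and 0 adjusted over the list alone), with Cyp51 2.65-fold and Fdps 2.61-fold lower. Of 19 glycolysis and hypoxia genes 10 fell and 1 rose (10 and 1 adjusted over the list alone), with Pgk1 2.18-fold lower. Mmp13, a collagenase of cartilage and bone (chromosome 9, 7272514 to 7283333), rose 8.14-fold to 69.4 ± 0.964 CPM (log2 3.02, SE 0.11), and Cxcl12, the chemokine that retains blood stem cells in marrow, from 8331 ± 2120 to 18050 ± 1580 CPM. In all, 5136 genes changed, 2580 higher and 2556 lower (2551 and 2594 with RLE size factors), and 678 and 469 of these changed at least 2-fold. Camera, which sets a list against all other genes, called 16 of 27 lists at its preset correlation and 0 with an estimated one, where the lowest adjusted p = 0.118 and 9 lists had an unadjusted p under 0.05. With an estimated correlation the adipocyte list had an adjusted p = 0.211, the mitosis list 0.14 and the SRF and MRTF targets 0.118, while fry, which asks whether a list moved one way on balance, called 21 of 26 lists. Fry does not set a list against the other genes, of which many changed (37.9% of tested genes were called). Here and below, its calls therefore do not show that a list moved more than other genes. The libraries of the groups did not overlap for 61.6% of the tested genes, where chance gives 10%. The gene Sap30l was among the most lowered, at 177 ± 258 CPM in Ctrl, because Ctrl replicate 1 stood at 475 CPM while the other Ctrl libraries were at 27.7 and 28.6 CPM, and without it the log2 change was -0.29. Its call was lost without CytoD replicate 3 (adjusted p = 0.0513).

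Lists of matrix, tubulin, nuclear lamina and signalling genes also held genes that changed after CytoD, as did 37.9% of all tested genes. Of 19 fibrillar matrix genes 11 fell and 3 rose (12 and 3 adjusted over the list alone), and of 15 matrix proteases and inhibitors 6 fell and 5 rose (6 and 6 adjusted over the list alone). Of 19 genes of actin turnover and nuclear transport 13 fell and 1 rose (14 and 1 adjusted over the list alone), and of 18 genes of the Arp2/3 complex and its activators 7 fell and 1 rose (7 and 1 adjusted over the list alone). Of 12 tubulins 10 fell and 0 rose (10 and 0 adjusted over the list alone), with Tubb6, a beta-tubulin, from 249 ± 19 to 85.9 ± 7.53 CPM. Of 12 genes of the nuclear lamina and its cytoskeletal links 7 fell and 1 rose (8 and 1 adjusted over the list alone), with Lmnb1, lamin B1, 2.29-fold lower. Of 17 p53 targets 8 rose and 1 fell (10 and 2 adjusted over the list alone), with Cdkn1a, an inhibitor of cell cycle kinases, 1.62-fold higher. Of 9 Wnt targets 3 rose and 0 fell (3 and 0 adjusted over the list alone), with Axin2, a feedback inhibitor of Wnt signals, 4.36-fold higher from 0.691 ± 0.318 CPM. Of 11 inflammatory genes 4 rose and 2 fell (4 and 3 adjusted over the list alone), with the chemokine Cxcl1 4.03-fold higher, and of 16 interferon response genes 2 rose and 1 fell (1 and 0 adjusted over the list alone). Iigp1, an interferon-induced GTPase outside that list and among the most raised genes, was 22.1-fold higher from 0.533 ± 0.329 CPM. Of 14 genes of the unfolded protein and integrated stress responses 5 rose and 5 fell (5 and 5 adjusted over the list alone), and of 9 chondrocyte genes 1 rose and 2 fell (3 and 2 adjusted over the list alone). Even at its preset correlation, camera did not call the protease, Wnt, inflammatory, interferon, stress response and chondrocyte lists (adjusted p = 0.62, 0.186, 0.525, 0.165, 0.762 and 0.876). It called the other lists of this paragraph at that setting only.

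The next comparison asked what followed when branching of actin filaments was inhibited with CK666 alone. Adipocyte genes rose, and genes of the contractile apparatus, of cell adhesion and of matrix fell. Of 25 adipocyte genes, 23 rose and 0 fell (23 and 0 adjusted over the list alone). Cd36 (chromosome 5, 17781690 to 17888959) rose from 0.492 ± 0.0704 to 56.9 ± 12.1 CPM, 115-fold (log2 6.84, SE 0.26), Plin1 65.5-fold and Adipoq 37.2-fold. Lipe, the hormone-sensitive lipase, rose 52.0-fold from 2.78 ± 0.4 CPM, Cfd, the adipocyte protease adipsin, 86.3-fold from 0.188 ± 0.0333 CPM, and Fabp4 6.33-fold. Pparg rose 1.88-fold and Cebpa 2.24-fold. Of 19 osteoblast genes, 8 fell and 2 rose (8 and 2 adjusted over the list alone): Runx2 fell from 65.7 ± 1.66 to 52.7 ± 7.15 CPM, a call lost when the fit held these 2 groups alone (adjusted p = 0.0594), and Smpd3, a sphingomyelinase needed for bone mineral, was 5.33-fold lower. Alpl was measured at 3.86 ± 1.1 CPM in Ctrl and 4.91 ± 2.13 CPM in CK666 (adjusted p = 0.449), with a log2 change of -0.08 without CK666 replicate 3. Sp7 at 0.614 ± 0.523 and 0.281 ± 0.141 CPM (adjusted p = 0.229) was not called, but without Ctrl replicate 1 it was, at -1.66 log2 (adjusted p = 0.0412).

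All 15 SRF and MRTF targets fell after CK666 (15 adjusted over the list alone), with Fhl2 3.02-fold and Cnn2, calponin 2, 2.61-fold lower. The call of Srf itself, 104 ± 4.54 against 81.7 ± 19.1 CPM (adjusted p = 0.0472), was lost without Ctrl replicate 1, 2 or 3 or CK666 replicate 1 (adjusted p = 0.0542, 0.124, 0.0945 and 0.0871), with the length correction (adjusted p = 0.0792) and when the fit held these 2 groups alone (adjusted p = 0.138). Of 13 contractile genes 10 fell and 0 rose (10 and 0 adjusted over the list alone), with Acta2 4.34-fold lower, and of 22 YAP and TAZ targets 14 fell and 1 rose (14 and 2 adjusted over the list alone), with Ctgf 4.72-fold and Cyr61 1.96-fold lower. Of 22 focal adhesion genes and integrins, 18 fell and 0 rose (18 and 0 adjusted over the list alone), and Itga11, a collagen receptor subunit (chromosome 9, 62677855 to 62783979), fell from 91.5 ± 6.43 to 11.4 ± 1.31 CPM. Of 19 fibrillar matrix genes 14 fell and 3 rose (14 and 3 adjusted over the list alone), among them Thbs1, thrombospondin 1, from 17360 ± 1490 to 3037 ± 873 CPM, Lox, a collagen crosslinking enzyme, 3.43-fold lower, and Col3a1, 3.43-fold lower. Of 18 genes of the Arp2/3 complex and its activators 8 fell and 2 rose (9 and 2 adjusted over the list alone). Actr2 was 1.38-fold and Actr3 1.64-fold lower, and Wasf1, an activator of the complex, 3.08-fold higher.

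Of 20 mitosis genes, 18 fell and 0 rose after CK666 (19 and 0 adjusted over the list alone), with Top2a 1.65-fold lower, and of 21 DNA replication genes 15 fell and 0 rose (18 and 0 adjusted over the list alone). Among the most lowered genes were Sfrp4, a secreted Wnt antagonist (chromosome 13, 19623175 to 19632823), which fell from 18.3 ± 4.13 to 1.34 ± 0.516 CPM, and Lgr5, a receptor for R-spondins, which fell from 30.0 ± 1.85 to 2.48 ± 1.34 CPM. Apcdd1, which inhibits Wnt signals at the membrane, was among the most raised, 45.5-fold higher. In all, 5565 genes changed, 3040 higher and 2525 lower, and 551 and 588 of these changed at least 2-fold. More genes were lower than higher with RLE size factors (2658 higher and 2878 lower) and with DESeq2 (2842 and 3081). Without CK666 replicate 3 the count was 5816, with 2664 higher and 3152 lower. Camera called 15 of 27 lists at its preset correlation and 0 with an estimated one, where the lowest adjusted p = 0.0839 and 7 lists had an unadjusted p under 0.05. With an estimated correlation the adipocyte list had an adjusted p = 0.134, the osteoblast list 0.175 and the fibrillar matrix list 0.122, and fry called 21 of 26 lists. The libraries did not overlap for 50.1% of the tested genes (10% by chance).

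**Figure D2:**
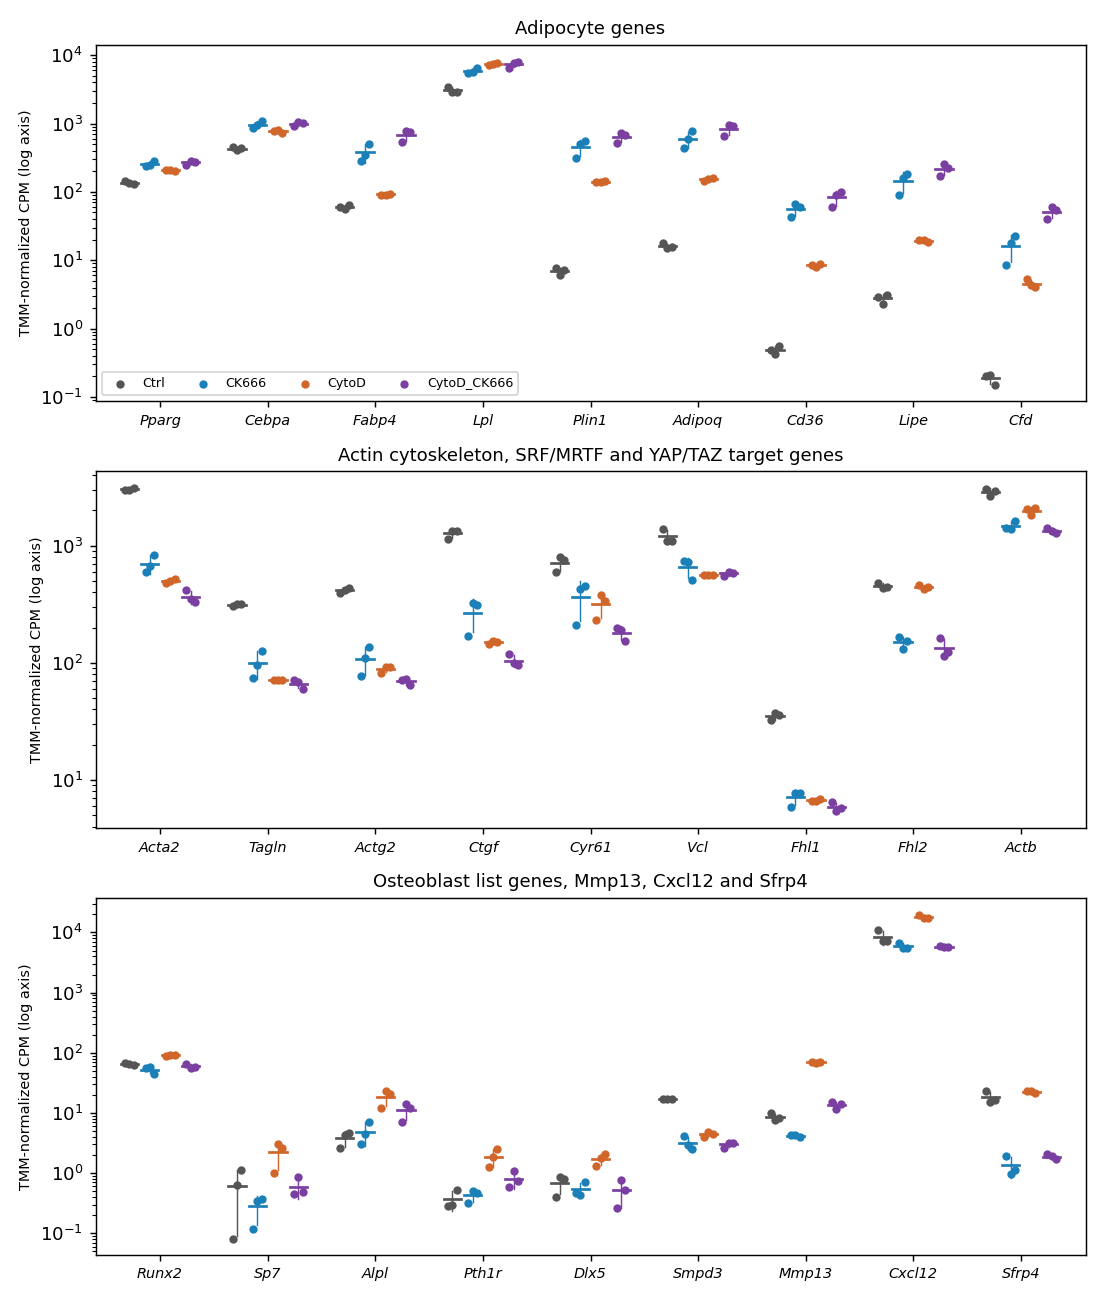
TMM-normalized CPM on a log axis for genes of 3 kinds in the 4 groups, with points for libraries, bars for group means and vertical lines for the SD (n = 3). Plin1 stood at 6.97 CPM in Ctrl, 141 in CytoD, 457 in CK666 and 645 with both, and Acta2 at 3042, 498, 700.5 and 367.

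Adding CK666 to CytoD raised adipocyte genes further and lowered some osteoblast genes. Of 25 adipocyte genes, 21 rose and 1 fell against CytoD alone (21 and 2 adjusted over the list alone), with Cfd 11.4-fold, Lipe 11.2-fold, Cd36 9.85-fold, Fabp4 7.48-fold and Adipoq 5.48-fold higher. Pparg and Cebpa rose 1.31-fold each. Lpl was measured at 7412 ± 167 CPM in CytoD and 7424 ± 823 CPM with both (adjusted p = 0.99), and the sign of this log2 difference of 0.00 turned under several settings. Of 19 osteoblast genes, 10 fell and 1 rose (11 and 1 adjusted over the list alone). Runx2 fell to 59.4 ± 4.5 CPM, 1.53-fold lower, and Dlx5, a homeobox factor of bone cells, from 1.73 ± 0.378 to 0.517 ± 0.252 CPM. Sp7 was measured at 0.595 ± 0.219 CPM (adjusted p = 0.0306), a call lost without CytoD replicate 2 or 3 or combination replicate 1 or 3 (adjusted p = 0.121, 0.0922, 0.0894 and 0.0976). The call of Pth1r at 0.811 ± 0.261 CPM was lost without CytoD replicate 3 or combination replicate 3 (adjusted p = 0.0778 and 0.0513). Alpl was measured at 18.6 ± 5.59 and 11.1 ± 3.55 CPM (adjusted p = 0.0986). It was called when the fit held these 2 groups alone (adjusted p = 0.0321) or took the replicate number as a block (adjusted p = 0.00268). Same-numbered libraries of these 2 groups correlated at 0.385, 0.108 and 0.334 in their deviations from the group means.

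Several genes that CytoD had raised fell with CK666 added: Mmp13 from 69.4 ± 0.964 to 13.6 ± 1.74 CPM, Cxcl12 from 18050 ± 1580 to 5746 ± 88.8 CPM and Vcam1, an adhesion molecule for blood cells, from 494 ± 28.0 to 180 ± 7.9 CPM. Sfrp4 and Sfrp2 were 11.9-fold and 7.87-fold lower, and Bmp4, a bone morphogenetic protein (chromosome 14, 46383520 to 46390599), fell from 65.7 ± 2.01 to 8.59 ± 0.797 CPM. Ogn, osteoglycin, was 9.77-fold lower and overlaps Cenpp. Of 19 fibrillar matrix genes 15 fell and 2 rose (16 and 3 adjusted over the list alone), with Col3a1 4.73-fold lower. All 20 mitosis genes fell (20 adjusted over the list alone), with Ccna2 2.24-fold and Plk1, a mitotic kinase, 2.15-fold lower, while of 21 DNA replication genes 8 fell and 1 rose (8 and 1 adjusted over the list alone). Of 20 cholesterol synthesis genes, 12 rose and 0 fell (15 and 0 adjusted over the list alone), with Hmgcs1 1.8-fold and Dhcr7 1.74-fold higher. Of 19 glycolysis and hypoxia genes 11 rose and 2 fell (11 and 2 adjusted over the list alone), with Bnip3 1.84-fold and Hk2, hexokinase 2, 1.8-fold higher. Of 13 contractile genes 7 fell and 0 rose (7 and 0 adjusted over the list alone). The call of Acta2, 1.36-fold lower, was lost without combination replicate 3 (adjusted p = 0.0557), and that of Ctgf, 1.43-fold lower, without any of the CytoD replicates or combination replicates 2 and 3 (adjusted p = 0.084 to 0.146). Mcam, an adhesion molecule of marrow stromal and perivascular cells, was 21.9-fold higher. In all, 4067 genes changed, 2134 higher and 1933 lower, but more were lower with RLE size factors (1829 higher and 2132 lower) and with DESeq2 (2044 and 2324). Camera called 15 of 27 lists at its preset correlation and 0 with an estimated one, where the lowest adjusted p = 0.188 (shared by the osteoblast, adipocyte and mitosis lists, among others) and 5 lists had an unadjusted p under 0.05, while fry called 20 of 26. The libraries did not overlap for 53% of the tested genes (10% by chance).

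**Figure D3:**
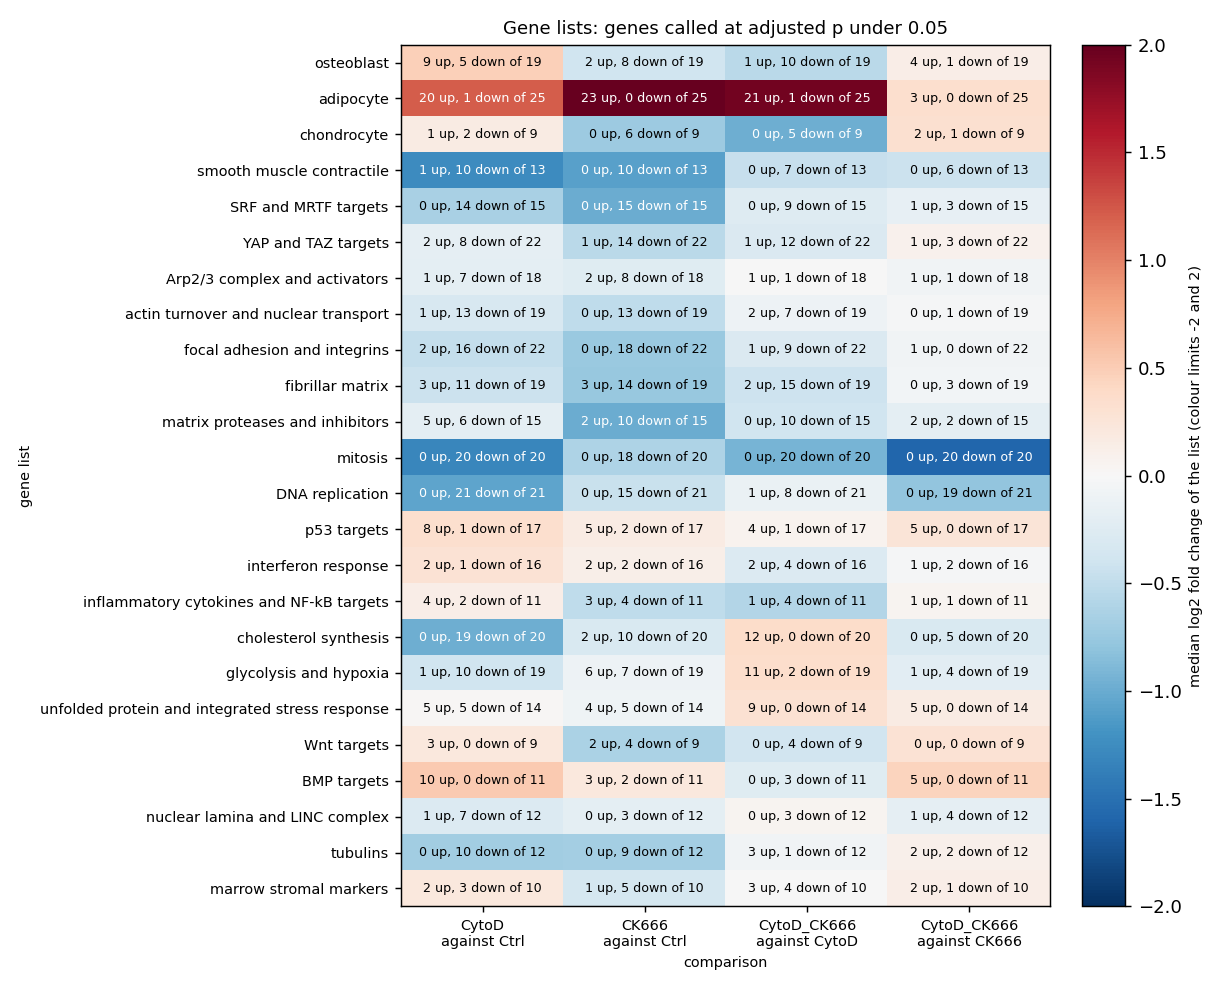
Gene lists with at least 9 tested genes (vertical axis) in 4 comparisons (horizontal axis), coloured by the median log2 fold change of the list with colour limits at -2 and 2, and with the numbers of genes called higher and lower at an adjusted p under 0.05. Adipocyte genes rose in the first 3 comparisons (20, 23 and 21 of 25), and 3 of 25 rose when CytoD was added to CK666.

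Adding CytoD to CK666 lowered cell division genes and raised a smaller number of adipocyte genes. All 20 mitosis genes fell (20 adjusted over the list alone), with Birc5, survivin, from 20.1 ± 1.46 to 4.97 ± 0.779 CPM, and of 21 DNA replication genes 19 fell and 0 rose (21 and 0 adjusted over the list alone). Cenpm, a centromere protein, was 3.93-fold lower. Of 25 adipocyte genes 3 rose and 0 fell (12 and 1 adjusted over the list alone), with Cfd 3.15-fold and Fabp4 1.8-fold higher, while Adipoq at 603 ± 160 and 836 ± 158 CPM did not pass the test (adjusted p = 0.0876). Adipoq was called with DESeq2 (adjusted p = 0.0412), with the length correction (adjusted p = 0.0104) and without CK666 replicate 3 (0.69 log2, adjusted p = 0.00659) or combination replicate 1 (0.62 log2, adjusted p = 0.0296). The call of Fabp4 was lost when the fit held these 2 groups alone (adjusted p = 0.083). Ism1, a secreted protein, rose 3.97-fold, Trib3, a stress-induced pseudokinase, 3.26-fold and Mmp13 3.23-fold. Of 19 osteoblast genes 4 rose and 1 fell (4 and 2 adjusted over the list alone). Alpl was 2.24-fold higher (adjusted p = 0.0422), a call lost without CK666 replicate 1 or 2 or combination replicate 2 or 3 (adjusted p = 0.108, 0.0706, 0.159 and 0.132) or when the fit held these 2 groups alone (adjusted p = 0.11), and Runx2 was at 52.7 ± 7.15 and 59.4 ± 4.5 CPM (adjusted p = 0.232). In all, 1570 genes changed, 599 higher and 971 lower. That number was 2563 without CK666 replicate 2, 745 and 778 without combination replicates 3 and 2, and 459 when the fit held these 2 groups alone. Without CK666 replicate 3 it was 2037, with 979 higher and 1058 lower. Camera called 10 of 27 lists at its preset correlation and 0 with an estimated one (lowest adjusted p = 0.112, shared by the mitosis and DNA replication lists, 4 lists with an unadjusted p under 0.05, and 10 of 26 called by fry). The libraries did not overlap for 27.6% of the tested genes (10% by chance).

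With both compounds against Ctrl, adipocyte genes rose and contractile, adhesion and cell division genes fell. Of 25 adipocyte genes 23 rose and 2 fell (23 and 2 adjusted over the list alone), with Cfd 272-fold, Cd36 168-fold, Plin1 92.4-fold, Adipoq 51.6-fold and Fabp4 11.4-fold higher. Ctgf was 12.2-fold lower, Lmcd1, a LIM domain protein, 11.2-fold lower and Acta2 8.29-fold lower. Dio3, which inactivates thyroid hormone (chromosome 12, 110279230 to 110281097), fell from 16.3 ± 1.08 to 1.43 ± 0.621 CPM. All 20 mitosis genes, all 21 DNA replication genes and all 15 SRF and MRTF targets fell (20, 21 and 15 adjusted over the list alone). Of 19 osteoblast genes 7 rose and 7 fell (7 and 7 adjusted over the list alone). Alpl was 2.87-fold higher, while Runx2 (adjusted p = 0.222) and Sp7 (adjusted p = 0.967) were not called. Runx2 was called when the fit held these 2 groups alone (-0.18 log2, adjusted p = 0.0287) and with the length correction (-0.16 log2, adjusted p = 0.0417). Spp1 was 1.49-fold lower (adjusted p = 0.0178), a call lost without combination replicate 2 or 3 (adjusted p = 0.084 and 0.083). In all, 6225 genes changed, 3303 higher and 2922 lower, but 3000 and 3176 with RLE size factors and 3142 and 3306 with DESeq2. Camera called 16 of 27 lists at its preset correlation and 0 with an estimated one (lowest adjusted p = 0.107, 8 lists with an unadjusted p under 0.05, and 23 of 26 called by fry). The libraries did not overlap for 63.4% of the tested genes (10% by chance).

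The interaction tested whether the change with CytoD differed in the presence of CK666. Adipocyte genes gained less from CytoD by fold when CK666 was present. Of 25, 13 had a negative and 1 a positive interaction (15 and 1 adjusted over the list alone). Negative ones included Plin1 (log2 -3.84, SE 0.26), Cd36 (log2 -3.54, SE 0.32) and Adipoq (log2 -2.76, SE 0.25). This holds for fold changes only. In mean CPM, Plin1 and Adipoq rose more from CytoD with CK666 present, from a higher level, although neither rise was called there. Pparg and Cebpa had interactions of -0.52 and -0.78 log2, and that of Fabp4 was 0.24 log2 (adjusted p = 0.568), but was called without CK666 replicate 3 (0.53 log2, adjusted p = 0.0406). Of 15 SRF and MRTF targets 11 had a positive and 0 a negative interaction (12 and 0 adjusted over the list alone), and of 13 contractile genes 10 a positive and 1 a negative one (10 and 1 adjusted over the list alone). Acta2 (1.68 log2), Tagln (1.56 log2), Ctgf (1.72 log2) and Fhl1 (2.11 log2) thus fell less from CytoD where CK666 was present. Of 22 focal adhesion genes 14 had a positive interaction and 0 a negative one (16 and 0 adjusted over the list alone), and of 20 cholesterol synthesis genes 13 a positive and 0 a negative one (16 and 1 adjusted over the list alone). The rise of Mmp13 with CytoD was smaller in the presence of CK666 (log2 -1.33). Cxcl12 rose with CytoD alone and stood at 5956 ± 738 CPM in CK666 and 5746 ± 88.8 CPM with both (log2 -1.17). The interactions of Runx2 (log2 -0.29, adjusted p = 0.152) and Alpl (log2 -1.10, adjusted p = 0.142) were not called in this fit. That of Runx2 was called without CK666 replicate 3 (log2 -0.38, adjusted p = 0.00701) and with the length correction (log2 -0.43, adjusted p = 0.0035). That of Alpl was called with the replicate number as a block (log2 -1.086, adjusted p = 0.00839), although the numbers did not pair all 4 groups. In all, 1935 genes had an interaction, 897 positive and 1038 negative. The number was 3396 without CK666 replicate 3, where more were positive (1936) than negative (1460). It was 1094, 1115, 1112 and 1114 without CytoD replicates 2 and 3 and Ctrl replicates 2 and 3. Camera called 15 of 27 lists at its preset correlation and 0 with an estimated one (lowest adjusted p = 0.171, shared by the SRF and MRTF targets, actin turnover and focal adhesion lists, against 0.32 for the adipocyte list, 5 lists with an unadjusted p under 0.05, and 16 of 26 called by fry).

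**Figure D4:**
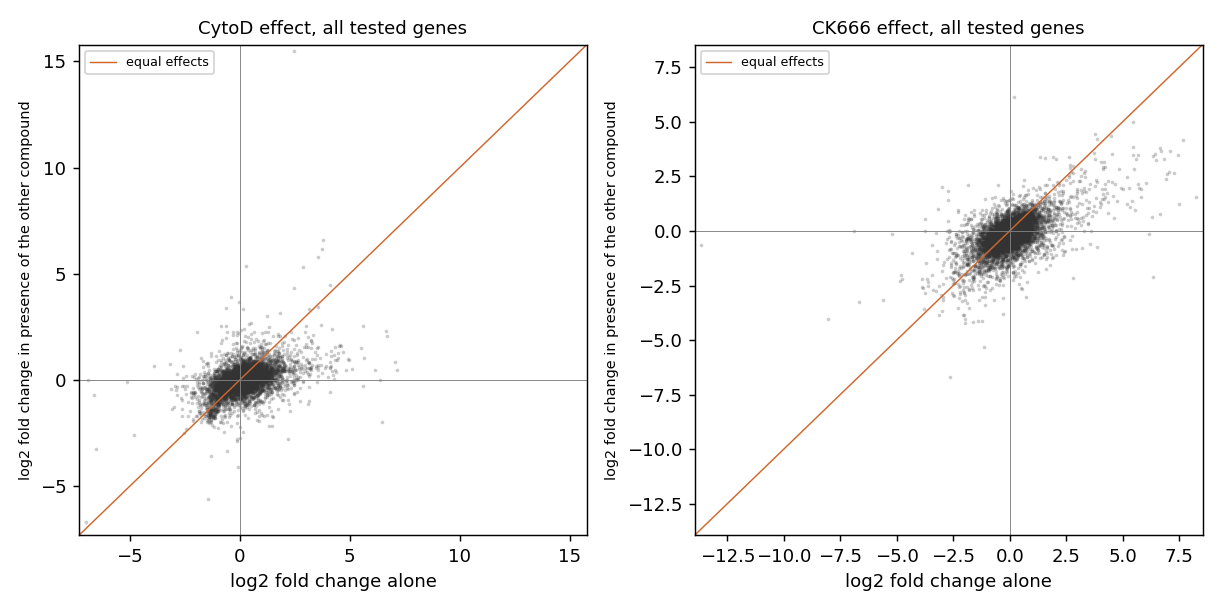
Log2 fold change of each tested gene with one compound alone (horizontal axis) and in the presence of the other (vertical axis), with one point per gene and a line where both are equal. The least-squares slopes of the second on the first were 0.302 for CytoD and 0.437 for CK666. Noise in the horizontal values lowers such slopes even where effects are equal, so they do not measure how much the effects shrank.

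The changes made by a compound alone and beside the other one were compared across genes, in sets of libraries with none in common. For CytoD the Pearson correlation was 0.438 and the Spearman correlation 0.415, and for CK666 they were 0.587 and 0.5, across genes that are not independent replicates. The Pearson values depended on the filter on low counts, with 0.13 and 0.164 without one and 0.534 and 0.678 with a stricter one. Of 2580 genes that CytoD raised alone, 362 were also raised and 39 lowered when it was added to CK666, and 881 of them had an interaction toward 0 and 1 away from it. Of 2556 lowered genes the numbers were 617, 27, 801 and 10 in the order lowered, raised, toward 0 and away.

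CK666 was also set against CytoD, a comparison added after the data had been examined. Bone and fat cell genes differed in opposite directions: of 19 osteoblast genes 14 were lower and 1 higher in CK666 (14 and 1 adjusted over the list alone), and of 25 adipocyte genes 20 were higher and 2 lower (20 and 2 adjusted over the list alone). Runx2 was 1.73-fold, Alpl 3.76-fold and Mmp13 16.5-fold lower with CK666 than with CytoD, and Sp7 stood at 0.281 ± 0.141 against 2.21 ± 1.09 CPM (adjusted p = 0.00364). Adipoq was 3.95-fold, Fabp4 4.15-fold and Col15a1, a basement membrane collagen, 9.81-fold higher, whereas Lpl was 1.26-fold lower, a call lost without CK666 replicate 1 or CytoD replicate 3 (adjusted p = 0.0587 and 0.0584). Of 20 mitosis genes 19, of 21 DNA replication genes 20 and of 20 cholesterol synthesis genes 18 were higher with CK666 and none was lower (19, 20 and 18 adjusted over the list alone). In all, 5380 genes differed, 3104 higher and 2276 lower, and 2553 and 3071 after a correction for gene length in each library. A fit of these 2 groups alone gave 3558, with 1832 higher. Camera called 15 of 27 lists at its preset correlation and 0 with an estimated one (lowest adjusted p = 0.145, shared by the osteoblast, Wnt target and BMP target lists, 6 lists with an unadjusted p under 0.05, and 19 of 26 called by fry).

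Few marker genes of other marrow cells were expressed at a level that could be tested. Of 16 macrophage genes 7 passed the count filter, of which 2 rose and 0 fell after CytoD (2 and 0 adjusted over the list alone), and the general leukocyte gene Ptprc had 0 counts in all 12 libraries. Lyz2 and Mpeg1, expressed in macrophages, rose after CytoD from 1.56 ± 0.353 to 5.33 ± 0.91 CPM and from 0.602 ± 0.256 to 3.23 ± 0.499 CPM. Of 13 endothelial genes 4 passed the filter, and of 10 erythroid and lymphoid genes found 1 did. Of these, 2 endothelial genes and the erythroid or lymphoid gene rose after CytoD, and 2 and 0 after CK666 (2 and 1 adjusted over the list alone in both). Of 10 marrow stromal marker genes tested 2 rose and 3 fell after CytoD (3 and 3 adjusted over the list alone), and 1 rose and 5 fell after CK666 (2 and 5 adjusted over the list alone). The share of reads not counted in gene rows, derived from the RPKM totals, was 11.2% ± 0.314 in Ctrl, 12.3% ± 0.227 in CK666, 13.1% ± 0.653 in CytoD and 13.5% ± 0.463 with both.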

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

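Among the tests below, the length correlation and the response slope for CK666 replicate 3, the ratios by direction for the compounds together, and the TMM ratio, the shares of the highest genes and the vomeronasal ratio for olfactory receptor genes, were chosen after the result was seen.

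The change with CytoD differed between cells with and without CK666 for 1935 genes, by the test of the interaction itself. Among adipocyte and related genes the interaction was -3.84 log2 for Plin1, -3.54 for Cd36, -2.76 for Adipoq, -0.78 for Cebpa and -0.52 for Pparg, and it was -3.52 for Tlr8, a receptor for RNA in endosomes. Among contractile and actin-linked genes it was 1.68 log2 for Acta2, 1.56 for Tagln, 1.72 for Ctgf and 2.11 for Fhl1, and it was 2.28 for Ptgs2, an enzyme of prostaglandin synthesis, and 2.1 for Klhl30. It was 1.18 log2 for Itga11, 1.12 for Itga5 and 0.98 for Cyp51. For the secreted factors Mmp13, Cxcl1 and Cxcl12 it was -1.33, -2.21 and -1.17 log2. The median interaction was -0.782 log2 over adipocyte genes, -0.384 over BMP targets and -0.282 over mitosis genes. It was 0.864 over contractile genes, 0.813 over tubulins, 0.662 over cholesterol synthesis, 0.652 over SRF and MRTF targets, 0.457 over the unfolded protein and integrated stress responses, 0.44 over focal adhesion genes, 0.379 over fibrillar matrix, 0.315 over YAP and TAZ targets, 0.265 over glycolysis and hypoxia, 0.241 over DNA replication, 0.239 over actin turnover and 0.149 over the Arp2/3 complex and activators. These are the 15 lists that camera called for the interaction at its preset correlation, and with an estimated one it called 0 (5 at an unadjusted p under 0.05; fry called 16 of 26).

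Most genes that CytoD changed and that had an interaction had one against the direction of their CytoD change. On the log2 scale, CytoD thus moved them less, or the other way, where CK666 was present. The interaction went toward 0 for 881 genes raised and 801 lowered by CytoD, and away from it for 1 and 10. Mitosis genes did not follow this, with a median CytoD change of -1.312 log2 alone and -1.581 in CK666. Genes were chosen without 1 replicate of Ctrl and CytoD at a time, and the median CytoD change in CK666 was 0.351, 0.302 and 0.285 of that in the left-out replicates, which argues against selection on shared libraries. The number of interactions was 3396 without CK666 replicate 3, which argues against that library as the source. It was 1960 with RLE size factors, but these moved the interaction by a median of only 0.0083 log2, too little to test normalization, so that other forms of it stay open. A wrong scaling constant would shorten the changes of raised or of lowered genes and lengthen the others, while the ratio was at most 0.329 for raised and 0.381 for lowered genes, which argues against such a constant. A difference in how the cells responded to CytoD once CK666 was present, which the design sets out to measure, stays open as a hypothesis and was not tested apart from these.

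CK666 replicate 3 stood apart from the other CK666 libraries. Its deviation from the mean of replicates 1 and 2 had a Pearson r of -0.659 with log2 gene length across genes. After a trend on length and GC content was removed, the median absolute deviation fell from 2.548 to 1.351 times the difference between replicates 1 and 2. The interval of 1.295 to 1.394 comes from resampled genes, which are not independent. With equal noise this ratio would lie under 1, since a mean of libraries varies less than a single library. The fall goes with a length and GC trend, which took 54.7% of the variance of the deviation, but part of the difference stayed. The corrected deviation also rose with the CK666 change measured in CytoD, with a slope of 0.125 (SE 0.007 over resampled genes). A larger response in that library thus stays open beside the trend.

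Counts on olfactory receptor genes, which the comparisons did not use as a group, summed to 11.41 CPM in CK666, 14.34 in CytoD and 12.53 with both, against 10.08 in Ctrl. The ratio of CytoD to Ctrl was 1.426 (95% interval 1.302 to 1.563, counting error only) and 1.339 after TMM scaling, where single CytoD and Ctrl libraries gave ratios of 1.247 to 1.482, which argues against scaling of the libraries. Of the counts, 96.5% lay on 10 genes, which argues against background spread evenly over the family, a test chosen when the vomeronasal result was known. Of the rise with CytoD, 92.2% lay on Olfr613 (4.97 CPM in Ctrl and 7.86 in CytoD) and Olfr856-ps1 (2.49 and 3.53). Between single libraries the share was 77.9% to 104.3%. Both genes together already held most of the 10.08 CPM in Ctrl, so a rise in proportion would also lie mostly on them. The share argues against a rise spread evenly over the genes of the family, but cannot decide about one in proportion. Without the 10 highest genes the ratio was 1.311 (0.767 to 2.269), which cannot decide, as the remaining genes hold few of the counts. Whether the rise came from transcription of these genes or from reads of other origin assigned to them was not tested. Vomeronasal receptor genes had a ratio of 1.3 (1.154 to 1.464, counting error only), with 1.02 to 1.559 between single libraries. At least 97.9% of their counts in each library lay on 10 genes, which argues against a background that reaches the genes of both families alike.

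Reads not counted in gene rows, a measure the comparisons did not use, made up 12.3% in CK666, 13.1% in CytoD and 13.5% with both, against 11.2% in Ctrl.

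Other splits of the compared libraries were run for each comparison. For the interaction, the labels of all 4 groups were shuffled over the 12 libraries. Of 45 splits 1, the real one, gave as many genes (1935, highest other 200). Such splits mix the changes made by each compound into the spread within groups, which lowers their calls. They therefore cannot decide whether the number of interactions arose by chance. As many lists came from 8 of 45 splits (15, highest other 17), so for the lists chance cannot be excluded. For comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05, and 1 of 10 gave as many genes or lists in each. The other splits put libraries of both groups on each side, so the difference between groups enters their spread and lowers their gene calls. The low numbers of genes from them therefore decide nothing about chance. The real and highest other numbers of genes were 5136 and 0 for CytoD against Ctrl, 5565 and 1 for CK666 against Ctrl, 4067 and 1 for both against CytoD, 1570 and 0 for both against CK666, 6225 and 0 for both against Ctrl, and 5380 and 0 for CK666 against CytoD. For lists they were 16 and 14, 15 and 12, 15 and 14, 10 and 9, and 16 and 15 in the first 5 of these.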

How the results depend on the processing

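The halved counts, the removal of Rn45s, the length correction and the comparison of CK666 with CytoD were chosen after the data were seen. Numbers of genes stayed within 1.5 times of the first value in all comparisons with RLE size factors, DESeq2, either filter, the replicate block, halved counts, removal of Rn45s and the length correction. Exceptions by direction were both against CK666 (higher: 1025 with DESeq2, 1000 length-corrected) and the interaction (lower: 1564 length-corrected). With the replicate block 5212 genes changed for CytoD against Ctrl, 5652 for CK666 against Ctrl, 4166 for both against CytoD, 1726 for both against CK666, 6299 for both against Ctrl and 2078 for the interaction. Replicate numbers did not pair the libraries by the rule set (11 of 18 correlations above 0.1, range -0.248 to 0.385), and 9 of 12 libraries correlated best with their own number. The median correlation was 0.1505 for libraries of the same number and -0.05 for others, so a pairing in part stays open. All 3 correlations were above 0.1 for Ctrl with CK666 and for CytoD with both, but not for the other pairs of groups. With the block Alpl was called for the interaction (-1.086 log2, adjusted p = 0.00839) and in both against CytoD (-0.753, adjusted p = 0.00268), Spp1 in CK666 against Ctrl (adjusted p = 0.0364) and in both against CytoD (adjusted p = 0.0404), and Ibsp after CytoD (adjusted p = 0.0499). Bglap (adjusted p = 0.0509) and Sap30l (adjusted p = 0.0584) after CytoD and Ctgf in both against CytoD (adjusted p = 0.0539) were not. Spp1, not called in the first fit, was also lower in CK666 against Ctrl with DESeq2 (adjusted p = 0.0347) and with no filter (adjusted p = 0.0424). The same held in the fit of these groups alone (adjusted p = 0.0125) and length-corrected (adjusted p = 0.026). In both against CytoD, Spp1 was called length-corrected (adjusted p = 0.0431) and without combination replicate 1 (adjusted p = 0.000233). A fit of the compared groups alone gave 459 genes (110 higher, 349 lower) for both against CK666, of which 458 were shared, and 3558 (1832 higher) for CK666 against CytoD, of which 3520 were shared, and 3982 to 7408 in the other 4 comparisons of groups. Without 1 library at a time, both against CK666 ranged from 745 to 2563 (higher 242 to 1144, lower 503 to 1419), the lowest without combination replicate 3, then 778 without replicate 2, and the highest without CK666 replicate 2. The interaction ranged from 1094 to 3396 (higher 506 to 1936, lower 569 to 1460), the highest without CK666 replicate 3 and the lowest without CytoD replicate 2 (1115 without CytoD replicate 3, 1112 and 1114 without Ctrl replicates 2 and 3). The cause was not tested. Camera called 0 lists in each of the 7 comparisons with an estimated correlation (fry: 21, 21, 20, 10, 23, 16 and 19 of 26; at an unadjusted p under 0.05: 9, 7, 5, 4, 8, 5 and 6).

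The correlations of effects alone and beside the other compound were 0.13 for CytoD and 0.164 for CK666 with no filter, 0.534 and 0.678 with the stricter filter, 0.507 and 0.642 with halved counts, and 0.385 to 0.484 and 0.522 to 0.628 without 1 library at a time. Directions that turned belong to genes without a call: Lpl in both against CytoD, 0.002 log2, was -0.025 with RLE and with DESeq2, -0.007 with no filter, -0.036 with the stricter one, -0.018 in the fit of the compared groups, -0.021 with halved counts, -0.016 without Rn45s, -0.026 length-corrected and -0.056 to 0.092 without 1 library. Sp7 in both against Ctrl, -0.041 log2, was 0.118 with the replicate block and -0.586 to 0.732 without 1 library, and Alpl in CK666 against Ctrl was -0.081 to 0.609. The cause was not tested. In the simulated data edgeR found 12% of genes changed by the smallest fold planted, 66% of those changed 1.5-fold and 93.9% of those changed 4-fold between 3 libraries and 3, and 0%, 32% and 91.8% for the interaction, with false calls of 2.4% and 5.1%, against 13.7% and 13.7% for DESeq2. Only 49 or 50 genes were changed at each fold there, of 13362 tested. In the real data 37.9% of genes were called for CytoD against Ctrl, so these rates may differ there. The simulated counts also used the spread that edgeR estimated, alike in all groups. No simulated library was made to stand apart as CK666 replicate 3 did. The rates therefore do not rank edgeR and DESeq2 on the real data.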

Other observations

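The genes described here were picked after the data were seen, and no explanation of them was tested. Lamin, tubulin and stress response genes were among those that changed. Of all tested genes, 41.1% changed after CK666 and 30.1% when CK666 was added to CytoD. Lmnb1, lamin B1, stood at 63.2 ± 8.91 CPM in Ctrl, 41.7 ± 2.09 in CK666, 27.6 ± 2.03 in CytoD and 15.4 ± 0.816 with both (SD, n = 3), and fell in CytoD and CK666 against Ctrl and in both against CytoD. Tubb6 was 2.18-fold lower in CK666 than in Ctrl. Of 12 tubulins 9 fell and 0 rose after CK666 (9 and 0 adjusted over the list alone). Of 14 genes of the unfolded protein and integrated stress responses 9 rose and 0 fell when CK666 was added to CytoD (9 and 0 adjusted over the list alone), with Dnajb9, a chaperone of the endoplasmic reticulum, 1.61-fold higher. Of 15 matrix proteases and inhibitors 10 fell and 0 rose in that comparison (10 and 0 adjusted over the list alone), and after CK666 alone Plau, urokinase, was 4.36-fold and Adamts1 4.82-fold lower. Camera's adjusted p for these lists was lost with an estimated correlation: 0.241 for tubulins after CK666, 0.195 for the stress responses and 0.188 for the proteases.

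Axin2, a target and inhibitor of Wnt signals, rose 3.52-fold after CK666, while Nkd1, also a Wnt target, was 3.02-fold lower. The chemokine Cxcl1 stood at 3.41 ± 0.597 CPM in Ctrl, 13.7 ± 0.927 in CytoD and 6.8 ± 1.21 with both, and was 2.02-fold lower with both than with CytoD.

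In some genes single libraries stood far from their groups. Tmem158 (chromosome 9, 123259057 to 123260789) was at 656.56 CPM in Ctrl replicate 2, 743.69 in CK666 replicate 3 and 460.18 in combination replicate 2, and at 2.13 to 4.25 CPM in the other 9 libraries. Accn1 (chromosome 11, 80880165 to 81968396) was at 87.32 CPM in Ctrl replicate 2, 483.76 in CytoD replicate 1 and 313.16 in combination replicate 1, and at 0.04 CPM or 0 in the others. Sap30l was at 475.39 CPM in Ctrl replicate 1 and at 21.35 to 29.39 CPM in the other 11 libraries. The number of genes with at least 1 count was 14983 to 15102 in Ctrl, 15172 to 15271 in CK666, 15621 to 15666 in CytoD and 15637 to 15642 with both. The 10 most counted genes took 11.2% of counts in Ctrl, 7.73% in CK666, 12% in CytoD and 8.28% with both.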
